A study of Mus musculus with 9 samples.

How the data were processed

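RNA of L8057 cells was measured on 9 one-colour short-oligonucleotide arrays, 3 each for CBFb_KD, Ring1b_KD and Control. Per the labels' protocols, total RNA was primed with an oligo-dT primer carrying a T7 promoter, transcribed in vitro with biotinylated nucleotides and hybridised. The deposited values are on a log2 scale, from 3.227 to 15.355 over 45101 probe sets, as judged from their range. The software, background correction, summary and normalization behind the deposited log2 values are not given in the sources used here. Priming from the poly(A) tail and short probes limit what is seen to the probed part of each transcript, and a summary of probes compresses differences near the floor and near saturation. Probe sets for the 3' and 5' ends of Actb differed by 0.09 to 0.11 (group means, log2) and those of Gapdh by -0.01 to 0.05. Those of the transferrin receptor differed by 1.46 in Control, 1.25 in CBFb_KD and 1.32 in Ring1b_KD. Those of pyruvate carboxylase differed by 0.37 ± 0.12 (SD, n = 3) in Control, 0.32 ± 0.14 in CBFb_KD and 0.17 ± 0.31 in Ring1b_KD, where array 3 stood apart at -0.17. Among the mouse control probe sets, 1 of the middle part of pyruvate carboxylase was lower in Ring1b_KD (-0.397, limma adjusted p = 0.0219), and 2 of the 3 for 18S ribosomal RNA were higher in CBFb_KD than in Ring1b_KD, by 0.391 (limma adjusted p = 0.0418) and 0.699 (limma adjusted p = 0.0443).

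Before the data were examined, the groups, tests, gene lists, alternatives and the rule for named genes were fixed. A table whose array medians lay within 0.1 of each other was to be kept, and any other to be quantile normalized. The medians ran from 6.514 to 6.651, a range of 0.137, so the values were quantile normalized with limma, and the values as deposited became an alternative. The Ring1b_KD arrays had the highest medians (6.612, 6.64 and 6.651), and CBFb_KD array 1 the highest of the others (6.588). The shift thus followed a group, and quantile normalization removes it whether it is technical or biological. The 64 control probe sets were left out. A table pairing probe sets with the platform annotation gave 1 gene symbol for 34945 probe sets and several for 932, and 9160 were not listed, so they are unnamed here. Entrez identifiers matched the mouse gene table of GRCm38.p6 for 34754 of the single-gene probe sets, and 0 symbols changed. Each gene was represented by its single-symbol probe set with the highest mean over the 9 arrays, which gave 18193 genes. Among the named genes defined below, a called probe set of Cbfa2t3, of Hspa5 and of Pfkl went against the chosen one in Ring1b_KD. Other genes were not checked for this. No genome sequence was used here.

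Group means were fitted to all 9 arrays, which share one estimate of the spread, with lmFit and eBayes(trend = TRUE) in limma 3.58.1 (R 4.3.3), with a prior of 6.805 degrees of freedom. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each knockdown against Control, the knockdowns against each other, and a moderated F test over the 3 groups, which called 4689 genes (25.8%). The 24 gene lists held 607 symbols, of which 550 were measured. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists within a comparison, beside camera with an estimated correlation and fry. With an estimated correlation, 0 lists passed in any comparison, where camera with the preset correlation passed 8 in CBFb_KD and 2 in Ring1b_KD. By fry, which asks whether a list's genes move one way without comparing them with other genes, the adjusted p was 0.00291 for interferon response genes, 0.00678 for mitotic genes and 0.00654 for megakaryocyte and platelet genes in CBFb_KD, and 0.0349 for ER stress genes and 0.644 for mitotic genes in Ring1b_KD. Fry passed 13 lists in CBFb_KD, 2 in Ring1b_KD and 13 between the knockdowns. Those that passed fry and not camera in CBFb_KD were the core binding factor (0.00216), PRC2 (0.00216), RUNX1 target (0.041), hematopoietic transcription factor (0.0261) and Cdkn and p53 target lists (0.0138), and in Ring1b_KD the PRC1 list (0.0204). Between the knockdowns they were the core binding factor (0.00158), PRC1 (0.0126), PRC2 (0.00453), RUNX1 target (0.0163) and Cdkn and p53 target lists (0.0142). Members were also adjusted over the list alone.

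The named genes are Cbfb, Runx1, Runx2, Runx3, Rnf2, Ring1 and Bmi1, whatever their result, and in each knockdown the 10 called genes that rose and the 10 that fell most, with arrays of the groups not overlapping and the higher mean at or above the median gene (7.42). Added were up to 4 called members per list by smallest adjusted p, the 5 per direction strongest in both knockdowns, up to 5 called in opposite directions, and the 5 per direction that differed most between the knockdowns. Gene models without an assigned name were passed over.

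Both knockdowns share the Control arrays, so 100 simulations of unchanged groups sharing simulated controls gave the overlap, correlation and covariance with no effect. The fitting steps were tested on simulated data, in which 200 of 18193 genes were changed. At log2 changes of 0.5, 1 and 2 the CBFb_KD comparison recovered 75.9%, 98.6% and 100% of changed genes, with 5.1% of its calls false, and the Ring1b_KD comparison 60.9%, 100% and 100%, with 2.3% false.

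The replicate numbers in the labels were checked for pairing through the correlation of arrays' deviations from their group means. Between CBFb_KD and Control, arrays with the same number correlated at 0.203, 0.377 and 0.200, all over 0.1, so by the rule the numbers pair these 2 groups, although no label says what they share. Between Ring1b_KD and Control the values were -0.068, 0.044 and 0.153, and between the knockdowns 0.045, 0.104 and -0.038, so the numbers do not pair those groups. Arrays with different numbers ran from -0.346 to 0.147.

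The alternatives were the values as deposited, arrays centred on their medians, the brighter part of the genes, a variance without a trend, a robust variance, array weights, the mean of a gene's probe sets, all probe sets one by one, no probe sets of shared sequence, only the 6 arrays compared, the replicate number as a block, a floor of 2-fold, and each array left out in turn. When 1 array is left out, the remaining pair of its group is assumed to vary like the other groups. A block within the 6 arrays compared was added after the data were seen, as were the checks of lists and control probe sets under each scaling and without each array, and fry without the targeted genes. Figures were drawn with matplotlib 3.10.9 (python 3.11.15).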

Results

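Gene expression was measured in L8057 cells, a mouse megakaryocytic leukaemia line that takes on features of maturing megakaryocytes when given a phorbol ester. The cells carried a lentiviral short hairpin RNA against CBFb (CBFb_KD), a hairpin against Ring1b (Ring1b_KD) or a control construct (Control). CBFb is the non-DNA-binding subunit of the core binding factor, which pairs with RUNX proteins. Ring1b, encoded by Rnf2, is the catalytic ubiquitin ligase of Polycomb repressive complex 1 (PRC1). Puromycin and 50 nM of the phorbol ester TPA were added 48 h after infection, and RNA was taken 72 h later, after 3 days of TPA. Each group had 3 arrays, described by the submitters as biological triplicates. The labels do not say whether the cultures were infected separately, so the p-values measure the spread between these arrays. The 9 arrays held 45101 probe sets each, from which 18193 genes were tested, and the number of arrays limits the precision. Between arrays of one group the correlation over all probe sets other than controls was 0.995 to 0.997. Between arrays of different groups it was 0.987 to 0.994. The study's title concerns core binding factors bringing PRC1 to chromatin. The comparisons address which transcripts changed when either protein was targeted and how far the changes overlapped. Protein amounts were not analysed here, so CBFb or Ring1b called reduced below means that its transcript was lower.

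Both targeted transcripts were lower in the arrays labelled for their knockdown. Cbfb (chromosome 8, 105170674 to 105217989 on GRCm38.p6) fell from 12.37 ± 0.12 (SD, n = 3, log2 signal) in Control to 9.19 ± 0.11 in CBFb_KD, a 9.02-fold difference (log2 fold change -3.17, SE 0.085, limma adjusted p = 3.28e-10). In Ring1b_KD Cbfb stood at 12.23 ± 0.07 and did not pass the test (log2 fold change -0.13, limma adjusted p = 0.36), although it passed with the arrays centred on their medians (-0.30, limma adjusted p = 0.0378). Rnf2 (chromosome 1, 151469398 to 151500991 on GRCm38.p6) fell from 10.65 ± 0.08 in Control to 8.98 ± 0.08 in Ring1b_KD, a 3.17-fold difference (log2 fold change -1.67, SE 0.077, limma adjusted p = 3.31e-07). In CBFb_KD it stood at 10.55 ± 0.02 (log2 fold change -0.10, limma adjusted p = 0.479). Cbfb had 1 probe set and Rnf2 had 5, of which 3 fell in Ring1b_KD, by 1.67, 1.71 and 1.02 on the log2 scale, while the others had log2 fold changes of 0.07 and -0.12 and were not called.

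Among partners of the targeted proteins, Runx1, the DNA-binding partner of CBFb, rose 2.56-fold in CBFb_KD (log2 fold change 1.36, SE 0.174, limma adjusted p = 0.000216), and its log2 fold change in Ring1b_KD was 0.26 (limma adjusted p = 0.364). Another of its 6 probe sets rose in Ring1b_KD as well (0.44, limma adjusted p = 0.0168 over all probe sets). The difference between the knockdowns passed as well (1.09, limma adjusted p = 0.000786). Bmi1, a Polycomb ring finger partner of Ring1b, fell 1.86-fold in Ring1b_KD (log2 fold change -0.90, limma adjusted p = 3.03e-05) and had a log2 fold change of 0.01 in CBFb_KD (limma adjusted p = 0.947), and this difference between the knockdowns passed too (0.91, limma adjusted p = 8.34e-06). Runx3 had log2 fold changes of -0.19 in CBFb_KD and -0.11 in Ring1b_KD, and Ring1, the paralog of Rnf2, -0.10 and -0.24. None of these 4 values passed the limma test on the chosen probe sets. With the mean of a gene's probe sets Runx3 fell in both (-0.37 in CBFb_KD and -0.44 in Ring1b_KD), and Ring1 passed in Ring1b_KD with median centring (-0.40, limma adjusted p = 0.0214) or without Ring1b_KD array 2 (-0.35, limma adjusted p = 0.0312). Runx2 was not analysed here.

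**Figure D1:**
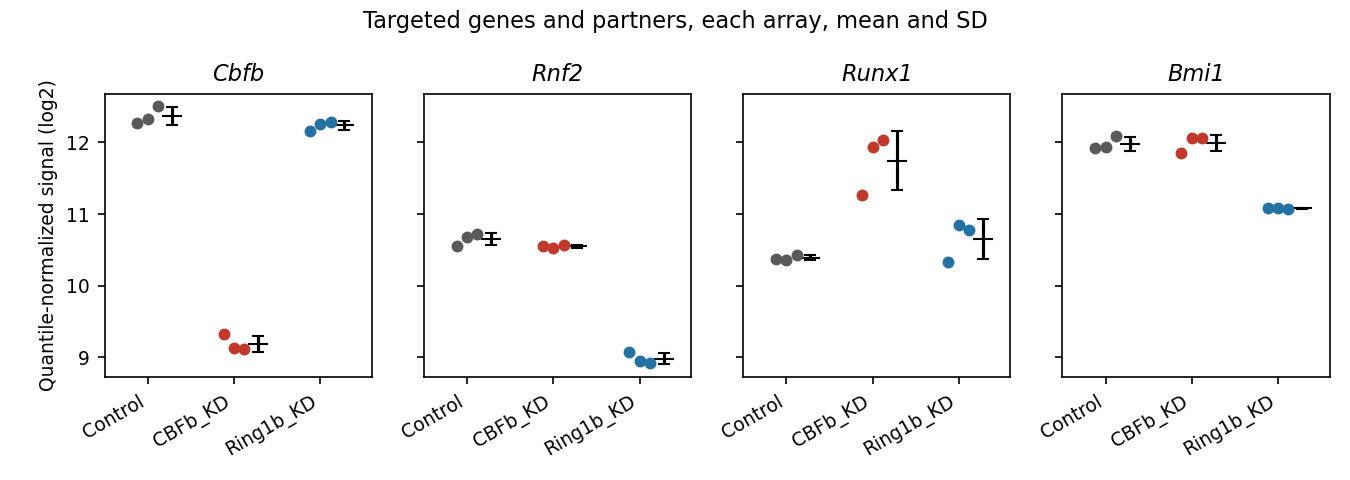
Quantile-normalized log2 signal of Cbfb, Rnf2, Runx1 and Bmi1 on each of the 9 arrays (points), with the group mean and SD beside them (n = 3). Cbfb averages 9.19 in CBFb_KD against 12.37 in Control, and Rnf2 averages 8.98 in Ring1b_KD against 10.65 in Control.

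With CBFb reduced, 24 of 31 interferon response genes and 14 of 36 megakaryocyte and platelet genes rose, and 26 of 29 mitotic and 22 of 28 DNA replication genes fell. Each of these lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.26 with an estimated correlation). F13a1, which encodes the A subunit of coagulation factor XIII, rose 8.6-fold, from 6.41 ± 0.47 to 9.51 ± 0.33 (SD, n = 3). Plek, which encodes the platelet protein pleckstrin, rose 5.75-fold, from 10.73 ± 0.29 to 13.26 ± 0.18. In all, limma called 2798 of 18193 genes at its adjusted p threshold of 0.05, 1416 higher and 1382 lower in CBFb_KD than in Control. Among changes of at least 2-fold the calls were mostly upward, with 182 genes higher and 26 lower. The 3 arrays of one group lay beyond all 3 of the other for 31.7% of genes, where chance gives 10%. The count was 1849 without CBFb_KD array 2 and 1751 without Control array 3.

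By the rule for named genes, the 10 largest increases in CBFb_KD ran from log2 fold changes of 3.35 to 2.28. They began with Csf2rb, which encodes the common beta subunit of the receptors for IL-3, IL-5 and GM-CSF, at 3.35 (SE 0.318, limma adjusted p = 2.9e-05). Its close paralog Csf2rb2 rose by 2.76, and since the sequences of the pair are nearly identical their separate values are uncertain. F13a1 (3.10), Cd24a (2.63), Plek (2.52), Glipr2 (2.39), Mxd1 (2.37), Gp9 (2.32), Exoc3l4 (2.31) and Ifit1 (2.28) followed. Cd24a encodes a surface glycoprotein, and Mxd1 a MAX partner that opposes MYC. After Cbfb the largest decreases were of Ms4a2, the beta chain of the IgE receptor, at -1.92 (SE 0.230, limma adjusted p = 0.000144), and of Naf1 (-1.47), Spns3 (-1.46), E2f8 (-1.44), Mtm1 (-1.40), Btnl9 (-1.32), Gzmb (-1.30), Tomm22 (-1.29) and Nkx1-2 (-1.27). E2f8 encodes an atypical E2F factor, Tomm22 a receptor of the mitochondrial outer membrane import pore and Gzmb granzyme B.

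Of 31 measured interferon response genes, 24 rose and none fell in CBFb_KD, and the count adjusted over the list alone was also 24 higher and 0 lower. Their median log2 fold change was 0.54, and the list passed camera against all other genes (adjusted p = 2.37e-16), but not with an estimated correlation (adjusted p = 0.26 with an estimated correlation). Ifit1, an interferon-induced RNA-binding protein, rose by 2.28, Oasl2, of the oligoadenylate synthetase family, by 2.16, and Irf7, a transcription factor of the type I interferon response, by 1.34 on the log2 scale. Among 29 mitotic genes 26 fell and none rose, with 26 lower and 1 higher adjusted over the list alone, a median of -0.51 and a camera adjusted p of 4.46e-16 (adjusted p = 0.26 with an estimated correlation). Aurkb, the kinase of the chromosomal passenger complex, fell by 1.07, Mki67, a marker of cycling cells, by 0.73, and Cenpe, a kinetochore motor, by 0.68 on the log2 scale. The number of mitotic genes called was 17 without Control array 3, and that of interferon response genes was 17 without CBFb_KD array 2. Of 28 DNA replication genes 22 fell and 1 rose, 23 and 1 adjusted over the list alone, with a median of -0.50 and a camera adjusted p of 6.23e-12 (adjusted p = 0.26 with an estimated correlation). Uhrf1, which recruits maintenance DNA methylation, fell by 1.03, and the helicase subunits Mcm7 and Mcm6 by 0.70 and 0.59. The member that rose was Ccnd3, a D-type cyclin, with a log2 fold change of 0.54. Without CBFb_KD array 2, 18 replication genes were called.

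Megakaryocyte and platelet genes formed the next group, with 14 of 36 measured members higher and 1 lower in CBFb_KD (15 and 1 adjusted over the list alone). The median log2 fold change was 0.27 and the camera adjusted p 1.31e-08 (adjusted p = 0.26 with an estimated correlation). Without Control array 3, 10 members were called. Gp9 and Gp5, subunits of the von Willebrand factor receptor, rose by 2.32 and 1.68, Treml1, a receptor of platelet alpha granules, by 1.82, and F2rl2, a protease-activated receptor, by 1.60 on the log2 scale. Itga2b, the platelet integrin alpha subunit, rose by 1.03 (limma adjusted p = 0.0169), a call lost without CBFb_KD array 2 or Control array 3. With a robust variance Itga2b was not called either (limma adjusted p = 0.0916). It was the 1 member that passed among 10 measured RUNX1 targets (1 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.314), and without either array that count was 0. Without Ring1b_KD array 3, or with the replicate number as a block, it was 2. The member that fell in the platelet list was Angpt1, which encodes angiopoietin-1, at -0.50, named after its value was seen.

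Erythroid genes rose in 12 of 27 cases and fell in 2 (15 and 3 adjusted over the list alone), with a median of 0.27 and a camera adjusted p of 4.42e-06 (adjusted p = 0.26 with an estimated correlation). Alas2, the erythroid enzyme that starts heme synthesis, rose by 1.61, Epb42, a red cell membrane protein, by 1.10 and Ank1, the erythroid ankyrin, by 0.79. The members that fell were Car1, a carbonic anhydrase (-0.72), and the transferrin receptor Tfrc (-0.57, named after its value was seen). Of 14 heme synthesis genes 3 rose and 1 fell (4 and 1 adjusted over the list alone), namely Alas2, Fech (0.36) and Urod (0.30) against Alad (-0.58), with a camera adjusted p of 0.0423 (adjusted p = 0.272 with an estimated correlation). That list call was lost with the replicate number as a block (camera adjusted p = 0.0644), with the arrays centred on their medians (0.0597), and without CBFb_KD array 1 (0.0953), Ring1b_KD array 1 (0.0538) or Control array 2 (0.0684). Its called members numbered 2 higher and 0 lower without Control array 1, and Alad also lost its call without CBFb_KD array 3, while Urod lost its own without any 1 of the Control arrays.

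Adhesion, actomyosin and matrix genes included 8 higher and 2 lower of 32 (12 and 2 adjusted over the list alone), with a median of 0.12 and a camera adjusted p of 0.00507 (adjusted p = 0.26 with an estimated correlation). Lgals1, the galectin-1 gene, rose by 1.83, Cnn2, a calponin, by 0.89 and Itga4, an integrin subunit, by 0.69, while Tagln2, an actin-binding protein, fell by 0.51. Of 20 ER stress and amino acid response genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.0127 (adjusted p = 0.272 with an estimated correlation). Dnajb9, a chaperone of the endoplasmic reticulum, rose by 0.96, and Ddit3, the transcription factor CHOP, by 0.77 on the log2 scale. The camera adjusted p of this list was 0.0743 without CBFb_KD array 1 and 0.0503 without CBFb_KD array 3, and 5 of its members were called without Control array 1.

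Lists of regulators held changes in both directions in CBFb_KD. Of 25 hematopoietic transcription factors 5 rose and 2 fell (the same counts adjusted over the list alone), and the list missed the camera threshold (adjusted p = 0.0579), which it passed without CBFb_KD array 2 (0.022), Control array 1 (0.0444) or Control array 3 (0.0465). With all arrays it had an adjusted p = 0.366 with an estimated correlation. Lyl1, a basic helix-loop-helix factor, rose 4.66-fold (log2 fold change 2.22, limma adjusted p = 6.6e-07), Fli1, an ETS factor of megakaryocytes, by 0.62 and Ldb1 by 0.48, while Ikzf1 fell by 0.70 on the log2 scale. Of 27 Cdkn inhibitors and p53 targets 6 rose and 2 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.0614, and 0.0444 without Control array 1, adjusted p = 0.304 with an estimated correlation and all arrays). Cdkn2b and Cdkn2a, which encode inhibitors of the cyclin D kinases, rose by 1.54 and 0.70, Trp53inp1 by 1.72, and Zmat3 fell by 0.93. Among 27 phorbol ester early response genes 6 rose and 2 fell (also adjusted over the list alone, camera adjusted p = 0.314), with Fosl2, an AP-1 subunit, at 1.77, Phlda1 at 1.58 and Myc at -0.74. This list had 4 higher and 1 lower without CBFb_KD array 3 or Control array 2, and 3 higher and 1 lower without Control array 3.

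Polycomb components went both ways when CBFb was reduced. Of 11 PRC2 subunits 3 rose and 4 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.455). By fry, which does not compare a list with other genes, the list was lower on balance (adjusted p = 0.00216), a call lost with median centring (adjusted p = 0.196). Called members were, among others, Jarid2 (0.69) and Phf1 (0.56) upward and Ezh2, the histone methyltransferase, (-0.61) and Suz12 (-0.60) downward. Without CBFb_KD array 2, Control array 2 or Control array 3 the list had 2 higher and 2 lower, and with median centring or without Control array 1 it had 3 higher and 2 lower. Of 20 PRC1 subunits 1 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.657), namely Phc3 (0.49), Cbx2 (-0.48), Pcgf6 (-0.47) and Phc1 (-0.34). With fewer arrays fewer members were called, namely 1 without CBFb_KD array 2 or Control array 2, 2 without CBFb_KD array 3, and 0 without Control array 3. Values moved less than calls in some cases. Without CBFb_KD array 2 Phc1 stood at -0.33 and Pcgf6 at -0.34, and without CBFb_KD array 3 they stood at -0.28 and -0.50. With the replicate number as a block 2 members rose and 3 fell. Among 7 core binding factor genes Runx1 rose and Cbfb fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.707), and the list was lower by fry (adjusted p = 0.00216) but not without Cbfb itself (adjusted p = 0.19). None of 33 Hox genes passed the limma test over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.707). Of 48 developmental regulators known as Polycomb targets 3 fell, Dlx1 (-0.40), Msx2 (-0.30) and Gata6 (-0.26), 0 adjusted over the list alone by limma and 4 at an unadjusted p under 0.05 (camera adjusted p = 0.992). Without CBFb_KD array 2 or 3 the count of these regulators was 0, and without CBFb_KD array 1 or any 1 Control array it was 1. Msx2 was not called as deposited.

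Among markers of other blood lineages no list passed camera in CBFb_KD, where 15.4% of all tested genes were called. Of 28 granulocyte and monocyte genes Csf2rb rose as given above, Prtn3, a neutrophil protease, rose by 1.42 and Ctsg, another granule protease, fell by 0.69, a call lost without any 1 CBFb_KD or Control array (2 and 1 adjusted over the list alone, camera adjusted p = 0.707). Of 15 mast cell, basophil and eosinophil genes Hdc, the histamine-forming enzyme, rose by 1.11 and 3 fell, Ms4a2, Kit (-0.39) and Mcpt1 (-0.39), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.912). The last pair lost their calls without CBFb_KD array 2 or Control array 2, Kit also without CBFb_KD array 3 or Control array 1, and Mcpt1 also without CBFb_KD array 1, Ring1b_KD array 2 or Control array 3. Of 20 stem, progenitor and endothelial genes Tie1 (0.91), Eng (0.80) and Slamf1 (0.73) rose and Kit fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.707), with 2 higher and 0 lower without CBFb_KD array 2, where Tie1 and Kit were not called. Of 17 glycolysis genes 4 rose, led by Aldoc (0.98) and Pkm (0.59), and 2 fell, led by Pfkl (-0.68), with 4 and 3 adjusted over the list alone (camera adjusted p = 0.642). No member was called by limma, over all genes or adjusted over the list alone, among 26 lymphoid (camera adjusted p = 0.707), 20 cholesterol synthesis (0.687) and 25 cytoplasmic ribosomal protein genes (0.992), each with 1 member at an unadjusted p under 0.05. Without CBFb_KD array 1 the lymphoid count was 1, and without Ring1b_KD array 3 the cholesterol synthesis count was 3, all lower. Median, mean and direction of the test differed in sign for the granulocyte, stem cell, glycolysis, ribosomal and Polycomb target lists.

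With Ring1b reduced, the largest increases by the rule for named genes were of Tnfrsf9 and Gzmb, and the largest decrease was of Crim1. Tnfrsf9, which encodes the costimulatory receptor 4-1BB, rose 11.6-fold, from 9.09 ± 0.16 to 12.63 ± 0.27 (SD, n = 3; log2 fold change 3.54, limma adjusted p = 5.78e-07). Gzmb, a cytotoxic granule protease, rose 7.48-fold, from 8.76 ± 0.69 to 11.66 ± 0.35. In all, limma called 2225 genes, 1029 higher and 1196 lower in Ring1b_KD than in Control, so that 46.2% of calls were upward. On the values as deposited the calls were 2591, of which 882 were higher and 1709 lower, 34.0% upward, and with the arrays centred on their medians they were 2895, of which 352 were higher and 2543 lower, 12.2% upward. The balance of higher and lower calls in Ring1b_KD thus rested on the scaling. As deposited, the Ring1b_KD arrays had the highest medians, and whether that shift was technical or biological was not tested. Changes of at least 2-fold numbered 33 in each direction. Groups did not overlap for 32.9% of genes, where chance gives 10%, and the number of calls was 1225 without Control array 2 and 1139 without Control array 3.

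After these, the largest increases in Ring1b_KD were of St8sia4 (2.35), Crem (2.19), Nr4a2 (1.89), Dgat1 (1.87), Btn1a1 (1.83), Gpr171 (1.77), Ears2 (1.73) and Pik3cg (1.73), given as log2 fold changes. St8sia4 encodes a polysialyltransferase, Crem and Nr4a2 inducible transcription factors, Dgat1 an enzyme of triglyceride synthesis and Pik3cg the catalytic gamma subunit of a phosphoinositide kinase. The call of Nr4a2 was lost without Ring1b_KD array 1 or 2 or Control array 1 or 3, with a robust variance and with the mean of its probe sets. The largest decreases were of Crim1 (-1.95), Mrpl18 (-1.73), Rnf2 itself, P2ry14 (-1.63), Ms4a2 (-1.49), Ei24 (-1.45), Gem (-1.45), Ptp4a3 (-1.41), Dag1 (-1.38) and Nop16 (-1.37). Crim1 encodes a transmembrane protein that binds growth factors, Mrpl18 a mitochondrial ribosomal protein, Gem a small GTPase, Dag1 dystroglycan and Nop16 a nucleolar protein. P2ry14, a receptor for UDP-glucose, lost its call without any 1 of the Control arrays or with a robust variance (limma adjusted p = 0.127).

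Hox genes and developmental regulators stayed mostly uncalled with Ring1b reduced, as did most genes, since 12.2% of all tested genes were called. Of 33 Hox genes 2 rose, Hoxa5 (0.34) and Hoxa11 (0.29), and Hoxd13 fell (-0.37), with 2 and 1 adjusted over the list alone (camera adjusted p = 0.998). Of 48 developmental regulators known as Polycomb targets 2 rose, Nkx2-9 (0.40) and Hand1 (0.30), and 0 passed limma when adjusted over the list alone, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.998). The Hox count was 0 without Ring1b_KD array 1 or any 1 Control array, and the count of developmental regulators was 0 without Control array 2 and 1 without Ring1b_KD array 2 or 3, CBFb_KD array 3 or Control array 1 or 3. The Hox list had 1 called member, higher without CBFb_KD array 3 and lower without Ring1b_KD array 3. Hoxd13 was also not called as deposited or without Ring1b_KD array 2. Hoxa5 was not called with median centring and stood at -0.02 with its probe sets of shared sequence left out. On each other scaling 1 of the developmental regulators was called, and Nkx2-9 was not. Among 20 PRC1 subunits Rnf2 and Bmi1 fell and Pcgf3 rose by 0.44 (1 and 2 adjusted over the list alone, camera adjusted p = 0.681), with Pcgf3 not called without Control array 2 or with median centring. The PRC1 list was lower by fry (adjusted p = 0.0204), but not without Rnf2 itself (adjusted p = 0.592). That call was also lost with the replicate number as a block (adjusted p = 0.156) and without CBFb_KD array 3, any 1 Ring1b_KD array, or Control array 2 or 3. As deposited 1 PRC1 subunit rose and 4 fell, and with median centring 0 rose and 6 fell. Of 11 PRC2 subunits Phf1 rose by 0.48, and Jarid2 (-0.43) and Aebp2 (-0.34) fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.998, fry adjusted p = 0.458). By fry PRC2 passed downward as deposited (adjusted p = 0.0396) and with median centring (adjusted p = 0.0318). Jarid2 lost its call without any 1 array other than Ring1b_KD array 2 or Control array 3. Of 27 Cdkn inhibitors and p53 targets 3 rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.853), with Cdkn1b, the p27 inhibitor, at 0.81 and Ei24 at -1.45. The balance of that list turned to 1 higher and 3 lower both as deposited and with median centring, and to 1 higher and 2 lower without Control array 3. It had 2 higher and 1 lower without Ring1b_KD array 1, Control array 1 or Control array 2.

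Gene groups that moved as sets in Ring1b_KD were few. Of 20 ER stress and amino acid response genes 5 fell and 2 rose (7 and 2 adjusted over the list alone), with a median log2 fold change of -0.18 and a camera adjusted p of 0.0135 (adjusted p = 0.998 with an estimated correlation). Nupr1, a stress-induced nuclear protein, fell by 0.53, and Hsp90b1, an ER chaperone, by 0.42, whereas Ddit4 rose by 0.89 and Dnajb9 by 0.53. Hspa5, the chaperone BiP, fell by 0.48 on its brightest probe set, while another of its 3 probe sets rose by 0.43. With the arrays centred on their medians 10 members fell and 1 rose. Of 29 mitotic genes 2 fell, Mki67 (-0.45) and Birc5 (-0.37), and 0 rose (4 and 1 adjusted over the list alone), with a median of -0.17 and a camera adjusted p of 0.0437 (adjusted p = 0.998 with an estimated correlation). As deposited 12 mitotic genes fell and with median centring 15, so the size of this shift depended on the scaling while its direction did not. The camera adjusted p was 0.051 without CBFb_KD array 3, 0.501 without Ring1b_KD array 2, 0.0703 without Control array 1 and 0.243 without Control array 3, and the 2 calls became 4 without CBFb_KD array 1 or 2 or Ring1b_KD array 3, 1 without Control array 2 and 0 without Control array 3.

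DNA replication genes missed the threshold in Ring1b_KD, with 5 of 28 lower and 1 higher (7 and 2 adjusted over the list alone, median -0.13, camera adjusted p = 0.0536). Ccne2, a cyclin of S-phase entry, fell by 0.92 and Cdc6, a licensing factor, by 0.66, and the primase subunit Prim1 rose by 0.32. The list passed as deposited (camera adjusted p = 0.000698), with median centring (0.002), and without CBFb_KD array 1 (0.044), CBFb_KD array 2 (0.0413), Ring1b_KD array 1 (0.0239) or Ring1b_KD array 3 (0.0031). These passes used the preset correlation, and with an estimated one the list did not pass on the quantile-normalized values (adjusted p = 0.998 with an estimated correlation). Its called members numbered 1 without any 1 Control array, 2 without Ring1b_KD array 2 and 3 without Ring1b_KD array 1. Cdc6 lost its call without Ring1b_KD array 2 or any 1 Control array, and Prim1 without Ring1b_KD array 3, any 1 Control array or on either other scaling. With median centring 10 members fell and 0 rose. Of 20 cholesterol synthesis genes Pmvk alone was called, at -0.28 (0 adjusted over the list alone and 4 at an unadjusted p under 0.05 by limma, median -0.06, camera adjusted p = 0.208). As deposited that list passed with 3 lower (0.00598), with median centring it passed with 5 lower (0.0298), and without Ring1b_KD array 3 it had 10 members lower (camera adjusted p = 4.5e-07), all with the preset correlation (adjusted p = 0.998 with an estimated correlation on the quantile-normalized values of all arrays). On that array the 3' and 5' probe sets of the pyruvate carboxylase control differed by -0.17, against 0.43 and 0.25 on the other Ring1b_KD arrays. A probe set of the middle part of that control was lower in Ring1b_KD (-0.397, limma adjusted p = 0.0219), a call lost without Ring1b_KD array 1 or any 1 Control array. The call of Pmvk itself was lost without any 1 array other than CBFb_KD array 1.

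No list of lineage genes passed camera in Ring1b_KD, where 12.2% of all tested genes were called. Of 36 megakaryocyte and platelet genes 1 rose and 5 fell (also adjusted over the list alone, camera adjusted p = 0.589). Rab27b, a GTPase of granule secretion, rose by 1.16, and Vwf (-0.75), the phosphatase gene Ptprj (-0.67) and Ltbp1 (-0.67) fell, but without Ring1b_KD array 3, Control array 1 or Control array 2 only 1 rose and 1 fell. Prkcq (-0.57) was the called member of 10 RUNX1 targets (1 and 1 adjusted over the list alone, camera adjusted p = 0.998), and 0 were called without those same arrays, while 2 were called as deposited. Among 25 hematopoietic transcription factors 2 rose and 4 fell (also adjusted over the list alone, camera adjusted p = 0.589), with Lyl1 at 0.81, Gata2 at -0.60 and Etv6 at -0.45. That list had 1 higher and 2 lower without Ring1b_KD array 1, Control array 1 or Control array 3. With the mean of its probe sets Etv6 stood at -0.14 and was not called (limma adjusted p = 0.437). Erythroid genes numbered 1 higher, Gypc (0.52), and 2 lower, Car1 (-0.64) and Ermap (-0.59), of 27 (1 and 3 adjusted over the list alone, camera adjusted p = 0.853). With median centring Gypc was not called and 3 erythroid genes were lower. Of 15 mast cell, basophil and eosinophil genes Fcer1a, the alpha chain of the IgE receptor, rose by 1.61 and Hdc by 0.99, while Ms4a2 and Gata2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.998), with Hdc not called without Ring1b_KD array 1 or 3 or any 1 Control array.

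The remaining lists in Ring1b_KD gave 0 camera calls on the quantile-normalized values, and the balance of higher and lower calls turned with median centring in the phorbol response, interferon, adhesion, heme synthesis and core binding factor lists. Of 27 phorbol ester early response genes 6 rose and 2 fell (7 and 5 adjusted over the list alone, adjusted p = 0.647), with Fosl2 at 1.62, Ier2 at 0.51 and Myc at -0.46. As deposited 6 rose and 4 fell, but with median centring 2 rose and 5 fell, where Ier2 was not called, and without Control array 3 2 rose and 1 fell. Of 31 interferon response genes 3 rose, Stat2 (0.49), Ddx58 (0.42) and Irf1 (0.39), and Eif2ak2 fell (-0.61), with the same counts adjusted over the list alone (adjusted p = 0.853). With median centring 1 rose and 2 fell, with Irf1 (limma adjusted p = 0.192) and Ddx58 (limma adjusted p = 0.295) not called, and as deposited Ddx58 was not called (limma adjusted p = 0.127). The list had 1 higher and 1 lower without Control array 2 or 3, where Stat2 and Ddx58 were not called, and Ddx58 was also not called without CBFb_KD array 3 or Ring1b_KD array 1 or 2. Glycolysis genes numbered 1 higher, Aldoa (0.42), and 2 lower, Pfkp (-1.13) and Pfkl (-0.45), of 17 (1 and 2 adjusted over the list alone, adjusted p = 0.998). On each other scaling Aldoa was not called and 3 members fell. Without Ring1b_KD array 1 or 2 or any 1 Control array, Pfkp was the member still called. With the mean of its probe sets, which disagreed in direction, Pfkl stood at -0.09 and was not called (limma adjusted p = 0.514).

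Granulocyte, lymphoid and stem cell markers gave few calls in Ring1b_KD, where 12.2% of all tested genes were called. Csf2rb rose by 1.15 and Ctsg fell by 0.80 among 28 granulocyte and monocyte genes (1 and 1 adjusted over the list alone, adjusted p = 0.998), Csf2rb not being called without Ring1b_KD array 1 or 2 or Control array 3, and Ctsg not without Control array 1 or 2. As deposited 4 rose and 1 fell in that list. With median centring 0 rose and 1 fell, where Csf2rb was not called (limma adjusted p = 0.0575). With a robust variance limma called neither Csf2rb (adjusted p = 0.13) nor Ctsg (adjusted p = 0.0507). Zap70 (0.50) and Cd8a (0.31) were higher among 26 lymphoid genes (2 and 0 adjusted over the list alone, adjusted p = 0.853). None of these was called by limma without Ring1b_KD array 2 or 3 or Control array 2 or 3, and Cd8a was not called without Ring1b_KD array 1, without Control array 1 (limma adjusted p = 0.0916) or with median centring. Cd8a stood at -0.02 with its probe sets of shared sequence left out. With the mean of a gene's probe sets limma called neither Zap70 (0.095, adjusted p = 0.367) nor Cd8a (0.117, adjusted p = 0.161). None of 20 stem, progenitor and endothelial genes was called by limma over all genes or adjusted over the list alone, and 7 had an unadjusted p under 0.05 (adjusted p = 0.998). One was higher as deposited or without Control array 1, 1 was lower without Ring1b_KD array 1 or Control array 3, 2 were lower with median centring, and 1 was higher and 1 lower without CBFb_KD array 1.

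Among the other lists in Ring1b_KD, Itgav (0.45) and Myl12a (0.25) were higher of 32 adhesion genes (0 adjusted over the list alone and 7 at an unadjusted p under 0.05 by limma, adjusted p = 0.853). Neither was called on either other scaling, where the list had 0 higher and 1 lower as deposited and 0 higher and 2 lower with median centring. It had 0 called members without CBFb_KD array 3, Ring1b_KD array 1 or Control array 2 or 3, 1 higher without CBFb_KD array 1 or 2 or Control array 1, 1 lower without Ring1b_KD array 2, and 5 higher without Ring1b_KD array 3. Uros (0.33) was higher among 14 heme synthesis genes (1 and 0 adjusted over the list alone, adjusted p = 0.589). On each other scaling Uros was not called and 2 heme synthesis genes were lower. The heme count was 0 without Ring1b_KD array 1 or any 1 Control array, 2 higher without Ring1b_KD array 2, and 1 higher and 1 lower without Ring1b_KD array 3. Cbfa2t3 (0.39), another probe set of which fell by 0.52, was higher among 7 core binding factor genes (1 and 0 adjusted over the list alone, adjusted p = 0.998). It was not called as deposited, with median centring (0.20, limma adjusted p = 0.34) or without Ring1b_KD array 1 or 2 or Control array 1 or 2, and with median centring that list had 0 higher and 1 lower. Rpl8 was lower, at -0.20, among 25 ribosomal protein genes (0 and 1 adjusted over the list alone, adjusted p = 0.589). Rpl8 was not called without Ring1b_KD array 1 or any 1 Control array, and with median centring 6 ribosomal protein genes fell (adjusted p = 0.0319 with the preset correlation, adjusted p = 0.998 with an estimated correlation on the quantile-normalized values). Median, mean and test differed in sign for the core binding factor, RUNX1 target, erythroid, mast cell, stem cell, Hox, Polycomb target and glycolysis lists.

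**Figure D2:**
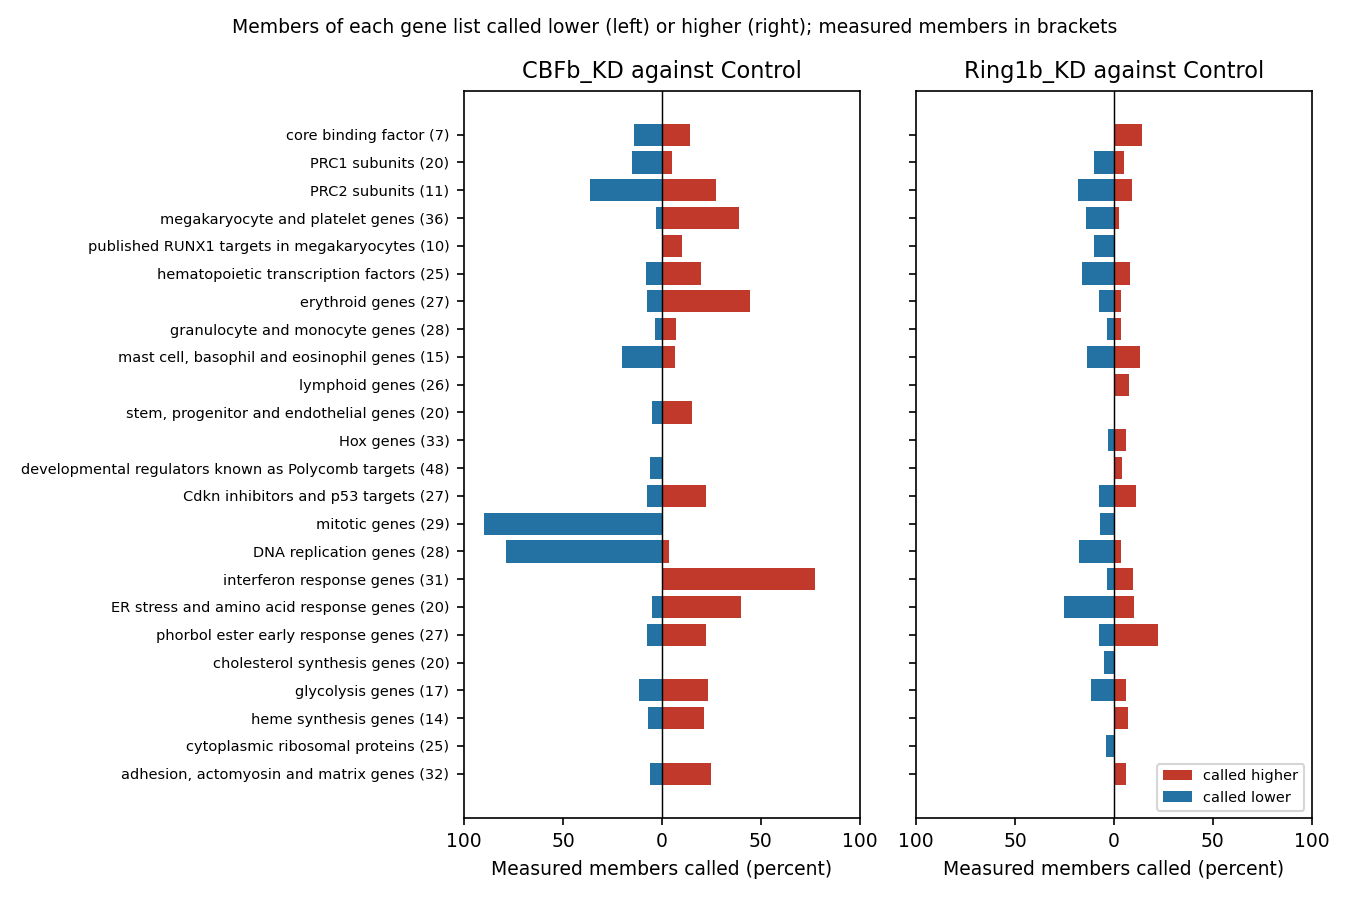
Percent of the measured members of each of the 24 gene lists called by limma in CBFb_KD (left) and Ring1b_KD (right) against Control, with higher genes to the right of 0 and lower genes to the left. In CBFb_KD 24 of 31 interferon response genes are higher and 26 of 29 mitotic genes lower, and in Ring1b_KD the mitotic bar stands for 2 lower genes, which are 12 on the values as deposited and 15 with median centring.

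Set against each other, the 2 knockdowns differed in 3536 genes, of which 1843 were higher and 1693 lower in CBFb_KD than in Ring1b_KD by limma (52.1% higher). On the values as deposited 3403 genes differed, 2118 higher and 1285 lower (62.2% higher), and with median centring 3238, 2726 higher and 512 lower (84.2% higher). The genes most in favour of CBFb_KD were Plek, with a log2 difference of 3.40 (SE 0.330, limma adjusted p = 2.14e-05), Exoc3l4 (2.70), F13a1 (2.62), Glipr2 (2.60) and Tent5c (2.57), a poly(A) polymerase gene. Those most in favour of Ring1b_KD were Gzmb, with a log2 difference of -4.21 (limma adjusted p = 7.78e-07), Tnfrsf9 (-2.90), Far2 (-2.21), which encodes a fatty acyl reductase, and Btn1a1 (-1.84), beside Cbfb itself (-3.04). Groups did not overlap for 33.8% of genes, where chance gives 10%. Control probe sets differed as well, with that of the B1 repeat higher in CBFb_KD by 0.548 (limma adjusted p = 0.00106) and those of the 3' and middle parts of 18S ribosomal RNA by 0.391 (limma adjusted p = 0.0418) and 0.699 (limma adjusted p = 0.0443). Both 18S calls were lost without CBFb_KD array 1 or 2, Ring1b_KD array 3 or Control array 2. The 3' one was also lost without CBFb_KD array 3, Control array 1 or Control array 3, and the middle one without Ring1b_KD array 2 and as deposited. Without Ring1b_KD array 3 the knockdowns differed in 2716 genes.

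The interferon response genes separated the knockdowns, with 22 of 31 higher in CBFb_KD and 0 lower (also adjusted over the list alone, median 0.62, camera adjusted p = 3.01e-11, adjusted p = 0.263 with an estimated correlation). Oasl2 differed by 2.44, Ifit1 by 1.90 and Irf7 by 1.28. Megakaryocyte and platelet genes had 15 of 36 higher and 0 lower (20 and 2 adjusted over the list alone, camera adjusted p = 7.29e-09, adjusted p = 0.271 with an estimated correlation), with Gp9 at 2.43 and Ltbp1 at 1.60. Erythroid genes had 12 of 27 higher and 0 lower (13 and 0 adjusted over the list alone, 1.88e-06, adjusted p = 0.263 with an estimated correlation). Of 20 ER stress genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone, 2.86e-06, adjusted p = 0.263 with an estimated correlation), among them Nupr1 (1.05), which rose in one knockdown and fell in the other. Hematopoietic transcription factors had 7 of 25 higher and 1 lower (also adjusted over the list alone, 0.00353, adjusted p = 0.316 with an estimated correlation), including Lyl1 (1.41), Gata2 (0.83) and Fli1 (0.80). Mitotic genes had 17 of 29 lower and 0 higher (24 and 0 adjusted over the list alone, 7.29e-09, adjusted p = 0.478 with an estimated correlation), and DNA replication genes 16 of 28 lower and 2 higher (18 and 2 adjusted over the list alone, 1.06e-05, adjusted p = 0.478 with an estimated correlation). Aurkb differed by -1.01 and Uhrf1 by -0.54. As deposited the mitotic count was 8 and with median centring 4, and it was 6, 7, 11 and 8 without CBFb_KD array 2, CBFb_KD array 3, Ring1b_KD array 1 and Ring1b_KD array 3. The replication count with median centring was 9 lower and 3 higher. Adhesion genes had 10 of 32 higher and 3 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.0461, adjusted p = 0.444 with an estimated correlation). This last call was lost without CBFb_KD array 2 (0.065) or Ring1b_KD array 3 (0.128), and the list had 6 higher and 2 lower without CBFb_KD array 3. Beside these lists stand the 18S and B1 differences given above. The other 16 lists did not pass camera in this comparison. By fry PRC2 subunits were lower in CBFb_KD (adjusted p = 0.00453), but the direction turned as deposited (adjusted p = 0.327) and with median centring (adjusted p = 0.0833), and the call was lost without Ring1b_KD array 3 (adjusted p = 0.0936). Of the 16 lists, cholesterol synthesis genes passed as deposited (0.0414) and without Ring1b_KD array 3 (5.2e-05), heme synthesis genes as deposited (0.0326) and with median centring (0.0436), and ribosomal protein genes with median centring (0.0382). With an estimated correlation, on the quantile-normalized values of all arrays, these lists had an adjusted p = 0.914 for cholesterol synthesis and 0.695 for heme synthesis and ribosomal protein genes. Median, mean and test differed in sign for the granulocyte, mast cell, lymphoid, phorbol response, cholesterol and glycolysis lists.

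The overlap of the changes seen with either transcript reduced was measured through the calls shared by the knockdowns. In the same direction 721 genes were called in both, 331 higher and 390 lower, which is 25.8% of the CBFb_KD calls and 32.4% of the Ring1b_KD calls. Independent lists of those sizes would share 80.1 higher and 90.9 lower genes, and simulated unchanged groups set against 3 shared simulated controls shared 0. Such groups had at most 1 call, so their 0 does not measure how far common controls raise the overlap of groups that do have calls. As deposited 229 shared genes were higher and 563 lower, and with median centring 128 and 694. In opposite directions 109 genes were called, 92 higher in CBFb_KD and lower in Ring1b_KD, where independent lists would give 93.1, and 17 the other way, where they would give 78.2. Of the 721 shared genes 152 (21.1%) also differed between the knockdowns. The 3 controls cannot be split into parts of at least 2 arrays, so part of the excess may come from the shared controls. The shared count was 475 without Control array 1, 418 without Control array 2 and 285 without Control array 3.

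Among the shared genes the strongest in both were Fosl2 (1.77 in CBFb_KD and 1.62 in Ring1b_KD), Crem (1.61 and 2.19), Nr4a2 (1.81 and 1.89), Cd200r1, an inhibitory receptor of myeloid cells (2.05 and 1.54), and Ccng2, a cyclin of non-dividing cells (1.86 and 1.41). Crem in CBFb_KD was not called without Control array 3, and Nr4a2 in CBFb_KD not without CBFb_KD array 2 or Control array 1 or 3, and in Ring1b_KD not without Ring1b_KD array 1 or 2 or Control array 1 or 3. With a robust variance limma lost Nr4a2 in both (adjusted p = 0.149 and 0.132), Crem in CBFb_KD (0.088) and Fosl2 in Ring1b_KD (0.0521). With the mean of its probe sets Nr4a2 stood at 0.919 in CBFb_KD and 0.951 in Ring1b_KD and was called in neither. Lower in both were Ms4a2 (-1.92 and -1.49), E2f8 (-1.44 and -0.94), Nop16 (-0.88 and -1.37), Nr1d2, a nuclear receptor of the circadian clock (-0.87 and -0.85), and Ydjc (-0.94 and -0.79). Gzmb (-1.30 and 2.90) and Far2 (-1.25 and 0.96) fell with CBFb reduced and rose with Ring1b reduced. Plek2 (0.82 and -1.07), the cathepsin gene Ctsl (0.81 and -0.77) and the phosphatase gene Ppm1e (0.83 and -0.77) went the other way. Across the 18193 genes, which are not independent replicates, the log2 fold changes of the knockdowns correlated at 0.335 (Pearson r) and 0.348 (Spearman rho). Simulated unchanged groups sharing simulated controls gave a Pearson r of 0.501. Simulated genes varied independently, so the simulated values do not carry a deviation of a real Control array. The covariance was 0.0215 against a simulated 0.0057, a difference of 0.0158. Fold changes had the same sign for 61.8% of genes, against 66.7% in the simulation.

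**Figure D3:**
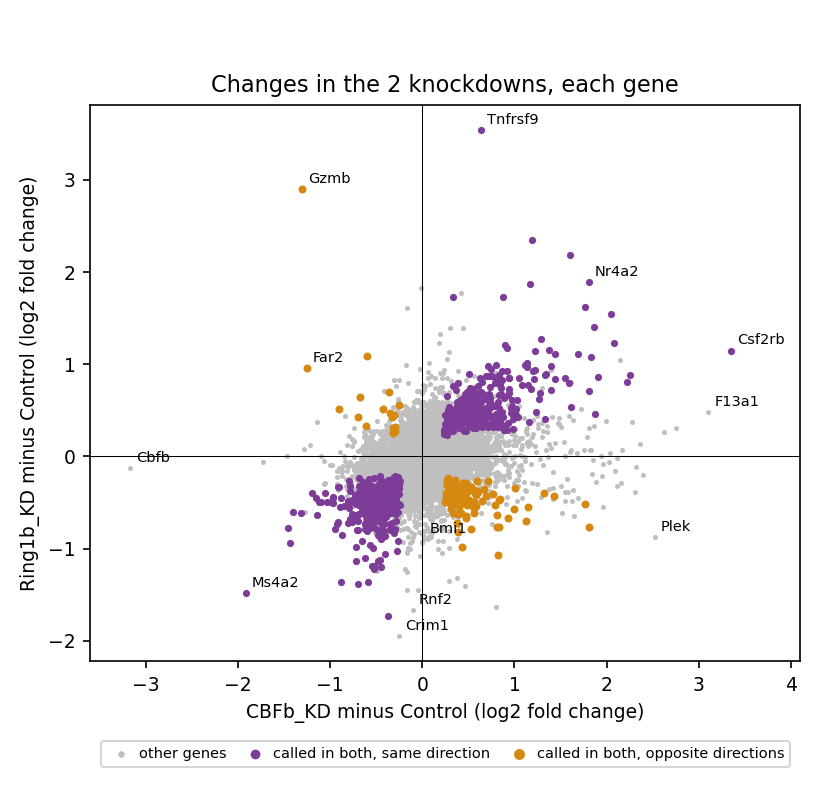
Log2 fold change of each of 18193 genes in CBFb_KD (horizontal axis) and Ring1b_KD (vertical axis) against the same Control arrays, with the 721 genes called in both in the same direction in purple and the 109 called in opposite directions in orange. Gzmb lies at -1.30 and 2.90, and Cbfb and Rnf2 lie near 0 on the axis of the knockdown that does not target them.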

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

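The tests of the interferon, cell cycle and shared-change patterns were chosen after those results were seen. The regroupings of the arrays were fixed before, but the count among those that part the pairs was added after.

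Signals outside the gene comparisons also differed from Control. A control probe set for the B1 repeat, a short interspersed element of the mouse genome, was higher by 0.33 (log2) in CBFb_KD (0.333, SE 0.083, limma adjusted p = 0.0241), with group means of 12.03 in Control, 12.36 in CBFb_KD and 11.81 in Ring1b_KD. That call was lost with median centring (0.315, limma adjusted p = 0.0573) and without CBFb_KD array 1 or 3 or Control array 2 or 3. The probe set differed between the knockdowns by 0.548 (limma adjusted p = 0.00106), and in Ring1b_KD it passed downward as deposited (-0.29, limma adjusted p = 0.0499) and with median centring (-0.376, limma adjusted p = 0.0213). Among 10092 probe sets without a single gene name, limma called 198 higher and 182 lower in CBFb_KD. In Ring1b_KD it called 298 higher and 173 lower. These totals, 380 and 471, are a smaller share than the 15.4% and 12.2% of tested genes called.

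Interferon response genes were higher in CBFb_KD, with a median log2 change of 0.54. A response to any hairpin would raise them in Ring1b_KD as well, where the median was 0.011. Of the 31 members 22 differed between the knockdowns, and both values argue against such a response. They cannot decide on the virus, since Control also carried a construct, and a response confined to the CBFb_KD virus was not tested. A single deviating array is argued against too as the source of that median, since the median nearest 0 was 0.485, without CBFb_KD array 2. Called members numbered 17 without that array, against 24 with all arrays. An effect of this hairpin outside its target may remain, and cannot be told apart from loss of CBFb because 1 group carried a hairpin against it. Loss of CBFb is the biological explanation the design names, and stays a hypothesis.

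Mitotic and DNA replication genes were lower in CBFb_KD, with 48 of 57 members called lower and a median of -0.505. Scaling between arrays is argued against, since on the values as deposited the 100 genes nearest in signal to each member had a median of -0.02 (SD 0.045 over members), against -0.50 for the members. One deviating array is argued against as well, as the median nearest 0 was -0.427, without CBFb_KD array 2. Slower division may follow from loss of CBFb or from an effect of the hairpin outside its target, which the single hairpin leaves open. No cell counts were analysed here.

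The 721 genes shared by the knockdowns rest on controls common to both. Over all tested genes, the covariance of the knockdowns' changes in excess of that from shared controls was 0.0158. It was 0.00836 without Control array 3, against 0.0184 and 0.0176 without Control arrays 1 and 2. Since these values have an SD of 0.00557, a deviating Control array 3 cannot be told apart from a shared effect. Carrying any hairpin rather than the control construct could also give shared changes, and 0 groups carried a hairpin against no mouse gene, so that explanation stays open as well. A shared action of CBFb and Ring1b is a possible biological explanation, and stays a hypothesis untested beyond these values.

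Other splits of the same arrays gave fewer calls. For each pairwise comparison the 10 splits of 6 arrays are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes, with 2798 in CBFb_KD, 2225 in Ring1b_KD and 3536 between the knockdowns, and 0 as the highest of the others. Of the 4 splits of CBFb_KD and Control that part all 3 same-numbered pairs, those other than the real one called 0. For the F test the real split was placed among 100 splits of the 9 arrays, the others being drawn. It alone gave as many as 4689 genes, and the highest other gave 1045. Of the 100 splits 42 part all 3 same-numbered pairs of CBFb_KD and Control, as the real one does. Among these too the real one alone gave as many, with 1045 as the highest other. The highest among splits that keep a pair together was 260. A random division of these arrays is thus unlikely to give the F test count. Chance differences between cultures are not excluded, since the labels do not say whether the cultures were infected separately.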

How the results depend on the processing

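The block within the 6 arrays compared, the checks of lists and control probe sets under each scaling and without each array, and fry without the targeted genes, were chosen after the data were seen. Cbfb in CBFb_KD and Rnf2 in Ring1b_KD kept their direction and call under every alternative run. Over 4018 repeats of named gene results, 3703 kept their direction and side of the threshold, 308 lost the call, 5 gained it and 2 reversed, Cd8a (-0.016) and Hoxa5 (-0.018) in Ring1b_KD without probe sets of shared sequence, where another probe set stands for the gene. With all probe sets tested one by one, which raises the number tested, calls were 4342 in CBFb_KD, 3820 in Ring1b_KD, 6033 between the knockdowns and 7978 by the F test. A floor of 2-fold left 208, 66, 224 and 334, and 17 shared calls, by its construction. Lists passing in Ring1b_KD were 4 as deposited, 5 with median centring and 0 in the brighter part of the genes, and the cause was not tested. By fry, megakaryocyte and platelet, erythroid, mitotic, DNA replication, interferon and core binding factor lists passed in CBFb_KD under each scaling, with the block and without each array. The other lists that fry passed in CBFb_KD did not pass with median centring. In Ring1b_KD both lists that fry passed, PRC1 and ER stress, were lost with the block and without CBFb_KD array 3, any 1 Ring1b_KD array, or Control array 2 or 3. Without the targeted genes, fry passed neither the core binding factor nor the PRC1 list in any comparison.

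Without 1 array at a time, which leaves fewer arrays, calls ranged from 1751 to 2995 in CBFb_KD, from 1139 to 2365 in Ring1b_KD and from 285 to 841 for shared genes. The lowest of each came without Control array 3, and counts over 1.5 times below the full one also came without CBFb_KD array 2 in CBFb_KD (1849), without Control array 2 in Ring1b_KD (1225), and without Control array 1 (475) or 2 (418) for shared genes. The correlation ranged from 0.254, without Ring1b_KD array 2, to 0.411, without Ring1b_KD array 3, and was 0.390 without Control array 1. Lists passing in Ring1b_KD ranged from 1, without CBFb_KD array 3, Ring1b_KD array 2, Control array 1 or Control array 3, to 4, without Ring1b_KD array 3, and the cause was not tested.

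With the replicate number as a block, calls were 3142 in CBFb_KD (2766 of the 2798 kept), 2611 in Ring1b_KD, 3938 between the knockdowns and 914 shared, and within the 6 arrays compared 3903, 2222, 2941 and 956. The block ended the call of the heme synthesis list in CBFb_KD and changed no other list call there, while in Ring1b_KD, whose numbers are not paired, the DNA replication list passed with it (camera adjusted p = 0.0319, adjusted p = 0.998 with an estimated correlation and no block). Of 202 named gene results 201 kept their direction and side of the threshold, the exception being Pmvk in Ring1b_KD, which lost its call. No value could be had for the F test with 6 arrays, nor for lists, correlation and targets under the 2-fold floor, and pseudocounts were not run since values are log2. Signals near the floor or saturation limit what the arrays resolve.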

Other observations

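The tests in this part were all chosen after the data were seen. A scan of 330 gene families, grouped by the stem of their symbols, found more groups lower than higher in CBFb_KD. Nucleoporin genes (Nup) fell in 12 of 19 cases and rose in 0, with a median log2 change of -0.35 and a camera adjusted p of 1.59e-06 (adjusted p = 0.94 with an estimated correlation). Genes of the RNA exosome (Exos) fell in 6 of 10, of the mitochondrial ribosome (Mrps) in 10 of 29, and of heterogeneous nuclear ribonucleoproteins (Hnrn) in 8 of 19, with 0 higher in each (adjusted p = 0.94 with an estimated correlation). The Nop, Utp and Rrp stems, which hold proteins of ribosome assembly, fell in 6 of 8, 5 of 11 and 5 of 8 cases with 0 higher (camera adjusted p = 0.00238, 0.00216 and 0.00314, adjusted p = 0.94 with an estimated correlation). Galectin genes (Lgal) rose in 6 of 10 cases with 0 lower (median 0.43, camera adjusted p = 0.00221), and Rab GTPase genes in 18 of 72 with 1 lower (median 0.07, camera adjusted p = 0.00255), both at an adjusted p = 0.94 with an estimated correlation. In Ring1b_KD the Nop genes fell in 5 of 8 cases (median -0.42, camera adjusted p = 0.000483, adjusted p = 0.983 with an estimated correlation). None of these family medians changed sign as deposited or with median centring.

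Lower MYC activity is a candidate explanation of the lower Nop, Utp and Rrp calls in CBFb_KD and of the lower Nop calls in Ring1b_KD, none of which passed camera with an estimated correlation. Myc fell by 0.74 in CBFb_KD (limma adjusted p = 6.32e-05) and by 0.46 in Ring1b_KD (limma adjusted p = 0.00267) on the log2 scale. A list of 47 growth and ribosome assembly genes bound by MYC, written after these results and sharing genes with those families, had 45 measured, of which 9 belong to families lower in CBFb_KD and 4 to the one lower in Ring1b_KD. In CBFb_KD 35 were lower and 0 higher, with a median of -0.441 (camera p = 2.31e-21, p = 0.0712 with an estimated correlation). In Ring1b_KD 16 were lower and 1 higher, with a median of -0.191 (camera p = 1.21e-08, p = 0.237 with an estimated correlation). Since the list was written after those families were seen and holds some of their genes, it restates them, and the question stays open in both knockdowns. Slower growth for another reason could give the same changes, and was not tested.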
